A study of Mus musculus with 57 samples.

How the data were processed

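RNA from the distal colon of C57BL/6 mice was measured on 57 Affymetrix whole-transcript arrays. Per the labels' protocols, total RNA was extracted with a mirVana kit, 250 ng was amplified and labelled with biotin by the WT Plus kit, and the mice were adults of 18 to 24 weeks. The treatment protocol names females. The deposited values are log2 expression values, 1 per probe set and array, made with RMA per the submitters' processing notes. RMA subtracts background, quantile-normalizes the arrays and summarises the probes of each set, so an array-wide shift in RNA content cannot be seen and changes of dim transcripts are compressed. The RMA software version and any filter are not given in the sources used here.

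The deposited table holds 41345 probe sets. The platform's probe table pairs 25335 of them with genes, of which 23521 carry exactly 1 symbol and 1814 carry several. The other 16010 are unnamed here and were not used in the comparisons, and no gene was named from a probe set with several symbols. For the 1082 genes with more than 1 probe set, the brightest was taken, which left 22180 genes. No dim gene was removed. Some members of the gene lists are not reported here. The probe table does not give which part of Insr its probe set covers.

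Samples were grouped by genotype and condition from their titles, and every column was matched to its sample. The labels call the samples biological replicates. They do not say whether a tumor and a colon sample came from the same mouse, so all samples were treated as independent.

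All comparisons used limma 3.58.1 in R 4.3.3 on the deposited log2 values, with lmFit, contrasts.fit and eBayes on a model of the 6 groups over all 57 arrays. Tests were two-sided with Benjamini-Hochberg adjustment over 22180 genes and a threshold of 0.05. The groups therefore shared an estimate of each gene's spread, with 51 residual degrees of freedom. Insr, Igf1r, Irs1 and Irs2 were also tested between genotypes by permutation, exact for the tumors (24310 arrangements) and with 100000 permutations elsewhere. The comparison tests were checked on simulated arrays of independent genes. For knockout against fl/fl tumors, 86.57% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 were called, with 10 false calls among 201. The simulated genes had the same spread in every group, and far more of them changed than passed between the real tumors. These shares are therefore not the power of the real genotype comparisons.

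Before the data were examined, 47 gene lists (24 of cell types, tissues and colon position and 23 of pathways), the model, the thresholds, most alternatives and the rule for naming genes were fixed. Of the lists, 46 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, adjusted over the 46 lists of a comparison. The preset does not allow for members that vary together across samples. The correlation estimated from the data was therefore run as an alternative, as was fry, which asks whether a list's genes move one way without setting them against other genes. A call that the estimated correlation ends is printed with that p.

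Genes were named by these parts of the rule: Insr, Igf1r, Irs1 and Irs2 in every comparison, up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold, and up to 4 members with the smallest adjusted p of each list described. Where no gene passed in a genotype comparison or an interaction, the 5 with the smallest p were named. Predicted models, small RNA genes, receptor and immunoglobulin segments, olfactory, vomeronasal and histone genes were counted and not named.

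The alternatives were a shift of all arrays to 1 median, a further quantile normalization, removal of dim genes, the mean of a gene's probe sets, an intensity trend with robust eBayes, a fit on the compared groups, array weights and the replicate number as a block. Alternatives chosen after seeing the data left out 1 array that stood apart, or added the mean of the squamous epithelium, distal colon position, B cell and T cell, or smooth muscle list as covariates. The difference of a list mean that would give a gene's change was that change over its slope on the list mean, both centred by group over all arrays. Values that the text gives per group were also searched for samples far from the rest with Dixon's criterion, over the 4 genes named above, the list means and the correlation between arrays. A list of small-intestinal transcripts was written after the main components of variation had been seen. The neighbours of Insr were taken from the gene order of assembly GRCm38.p6.

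Arrays have no read depth, and the number of arrays limits the precision. Array medians lay between 5.923 and 6.039, and the mean correlation of an array with the others of its group lay between 0.98148 and 0.99238. No pair of arrays correlated above 0.99447, so no array was a copy of another.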

Results

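Gene expression was measured in the distal colon of INSRfl/fl mice, which carry an insulin receptor gene flanked by loxP sites, and of villin-CRE-INSR-/- mice, in which that gene is inactivated in the intestinal epithelium (called knockout here). Mice were untreated or received AOM, a colon carcinogen, and DSS, which injures the colon epithelium. AOM was injected at 7.4 mg/kg, followed in week 2 by 7 days of 3% DSS, and tissue was taken in week 5, which the labels give as 3 weeks from the end of DSS although the weeks they name leave a shorter interval. The groups were untreated colon (10 fl/fl and 10 knockout), colon after AOM+DSS (10 and 10) and tumors after AOM+DSS (8 fl/fl and 9 knockout). Values below are log2 changes ± SE from limma unless stated otherwise.

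Insr, the insulin receptor, was lower in knockout than in fl/fl samples in every condition. In untreated colon its level was 8.04 ± 0.16 in knockout and 8.98 ± 0.16 in fl/fl samples (log2, SD, n = 10 each), or 52.3% of the fl/fl level (permutation p = 2e-05). After AOM+DSS it was 7.74 ± 0.16 against 8.58 ± 0.22 (SD, n = 10 each), or 55.8% (permutation p = 2e-05). In tumors it was 7.53 ± 0.36 (SD, n = 9) against 8.18 ± 0.235 (SD, n = 8), or 63.6% (exact permutation p = 0.00169). All 10 knockout samples lay below the lowest fl/fl sample in untreated and in AOM+DSS colon, and 2 knockout tumors lay above the lowest fl/fl tumor. These were replicate 6 at 7.79 and replicate 8 at 8.35, which lay above the mean of the fl/fl tumors. Why replicate 8 was so high was not tested. The limma changes were -0.94 ± 0.10 (adjusted p = 6.71e-09), -0.84 ± 0.10 (adjusted p = 2.32e-07) and -0.65 ± 0.11 (adjusted p = 0.00234). The tumor call was lost over all genes when the tumors alone were fitted (adjusted p = 1) and with array weights (adjusted p = 0.087). Samples hold epithelium with other cells, and the part of the level that comes from each was not measured.

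**Figure D1:**
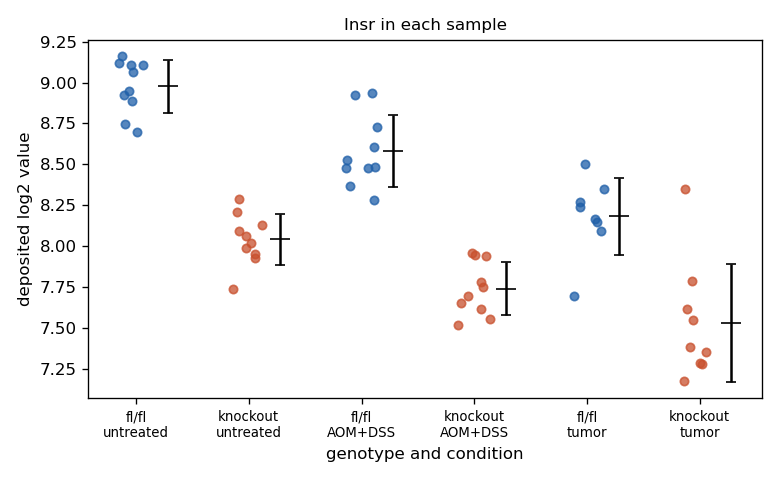
Deposited log2 value of Insr (vertical axis) in each of the 57 samples by genotype and condition (horizontal axis), with points for samples and bars for the mean ± SD. Group means were 8.98 and 8.04 in untreated fl/fl and knockout colon, 8.58 and 7.74 after AOM+DSS, and 8.18 and 7.53 in tumors.

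Igf1r, the receptor of insulin-like growth factor 1, and Irs1 and Irs2, adaptors of both receptors, passed the threshold over all genes in no genotype comparison. Irs2 was 0.53 ± 0.14 higher in untreated knockout colon (adjusted p = 0.397 over all genes, permutation p = 0.00087 alone). In that comparison Igf1r differed by 0.26 ± 0.092 (permutation p = 0.0167) and Irs1 by 0.19 ± 0.087 (permutation p = 0.0307). These p are not adjusted for the 12 tests of 4 genes in 3 conditions. After AOM+DSS the differences were Igf1r 0.22 ± 0.092, Irs1 0.030 ± 0.087 and Irs2 0.23 ± 0.14 (permutation p = 0.00597, 0.744 and 0.175). In tumors they were Igf1r -0.066 ± 0.10, Irs1 -0.047 ± 0.095 and Irs2 -0.045 ± 0.15 (exact permutation p = 0.59, 0.644 and 0.689). Of the 18 measured members of the insulin signalling list, Insr was the 1 that passed over all genes in each genotype comparison. Adjusted over the list alone, 2 members were higher and 1 lower in untreated colon, 1 was lower after AOM+DSS and 2 were lower in tumors. The list's own test gave adjusted p = 0.38, 0.647 and 0.0314 in these conditions, the last becoming adjusted p = 0.936 with an estimated correlation.

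The first question was how the colon of fl/fl mice after AOM+DSS differed in week 5 from untreated colon. Clca4b, of a family of calcium-activated chloride channel regulators, rose 24.9-fold, the acute-phase gene Saa3 9.60-fold and the cytokine Il1b 7.83-fold. Their log2 changes were Clca4b 4.64 ± 0.41, Saa3 3.26 ± 0.39 and Il1b 2.97 ± 0.33. The platelet chemokine Ppbp (4.54 ± 0.90), the retinol dehydrogenase Dhrs9 (3.11 ± 0.30), Plet1 (2.79 ± 0.41) and Ltf, which encodes lactoferrin (2.76 ± 0.71), were also among the 12 largest rises. The others were Krt6a 3.73 ± 0.86, Krt14 2.97 ± 0.53, Psca 3.17 ± 0.92, Tmprss11g 3.22 ± 0.70 and Tmprss11d 2.88 ± 0.72. Samples of a group differed widely in several of these genes. In untreated and AOM+DSS colon the log2 SD were 1.91 and 2.41 for Ppbp, 1.72 and 2.22 for Krt6a and 2.23 and 1.87 for Psca. They were smaller for Il1b (0.37 and 1.23) and Saa3 (0.36 and 1.31). The 12 largest falls were led by Mptx1, a mucosal pentraxin (-1.77 ± 0.33). They included the sugar phosphate transporter gene Slc37a2 (-1.55 ± 0.26), the magnesium channel gene Trpm6 (-1.15 ± 0.17) and the carotenoid-cleaving enzyme gene Bco2 (-1.38 ± 0.16). The other 8 were Fxyd4 -1.52 ± 0.31, St8sia5 -1.37 ± 0.22, Vsig2 -1.27 ± 0.19, Cpm -1.15 ± 0.18, Naaladl1 -1.10 ± 0.20, Hao2 -1.07 ± 0.33, Itih2 -1.01 ± 0.17 and Btbd35f1 -0.99 ± 0.37. Insr fell by 0.40 ± 0.10 (adjusted p = 0.00235), whereas Igf1r, Irs1 and Irs2 did not pass, at Igf1r 0.069 ± 0.092, Irs1 -0.13 ± 0.087 and Irs2 0.043 ± 0.14.

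In total, 5044 of 22180 genes passed in fl/fl mice, 2715 higher and 2329 lower, of which 210 rose and 15 fell at least 2-fold. With the squamous list's mean as a covariate, chosen after seeing the data, 3408 passed, of which 3149 were among the 5044. The balance of directions depended on scaling, with 3373 higher and 1254 lower after a shift to 1 median and 2254 higher and 2984 lower after a further quantile normalization. In knockout colon, described next, that normalization gave 3254 higher and 3975 lower.

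Immune lists rose in fl/fl colon after AOM+DSS. Of the macrophage list, 12 of 12 measured members rose over all genes and 12 adjusted over the list alone, among them Ms4a7 0.92 ± 0.094, Cd68 1.03 ± 0.11, C1qb 0.91 ± 0.10 and C1qa 0.76 ± 0.088. The macrophage median was 0.82, with adjusted p = 1.03e-20, and adjusted p = 0.00948 with an estimated correlation. Of the type I interferon response, 11 of 12 measured members rose over all genes and 11 adjusted over the list alone, led by Oasl2 1.87 ± 0.21, Ifit1 2.17 ± 0.26, Rtp4 1.42 ± 0.18 and Zbp1 1.65 ± 0.21. The type I interferon response median was 1.29, with adjusted p = 3.78e-14, and adjusted p = 0.0756 with an estimated correlation. For the interferon-gamma response, 14 of 15 measured members rose over all genes and 14 adjusted over the list alone, with Ido1 2.75 ± 0.35 and Gbp3 1.38 ± 0.21. The interferon-gamma response median was 0.84, with adjusted p = 3.68e-11, and adjusted p = 0.140 with an estimated correlation. T cell and B cell lists had 7 of 11 and 9 of 10 members higher, or 9 and 10 adjusted over the list alone, for example Cd3e 1.21 ± 0.16, Cd4 1.09 ± 0.16, Ms4a1 1.71 ± 0.35 and Cr2 1.46 ± 0.32. Their adjusted p of 3.58e-08 and 1.68e-07 became adjusted p = 0.109 and adjusted p = 0.172 with an estimated correlation. For neutrophil genes, 8 of 12 measured members rose over all genes and 9 adjusted over the list alone, with Csf3r 1.33 ± 0.22 and Clec4d 1.27 ± 0.22. The neutrophil median was 1.02, with adjusted p = 1.24e-05, and adjusted p = 0.163 with an estimated correlation. For mast cell genes, 7 of 9 measured members rose over all genes and 7 adjusted over the list alone, with Cpa3 1.73 ± 0.25 and Mcpt1 2.43 ± 0.38, which encode mast cell proteases. The mast cell median was 0.91, with adjusted p = 8.17e-07, and adjusted p = 0.121 with an estimated correlation.

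Stromal, epithelial and metabolic lists also moved. Of the fibroblast list, 9 of 13 measured members rose over all genes and 10 adjusted over the list alone, led by the collagen genes Col1a2 0.69 ± 0.10, Col3a1 0.67 ± 0.11 and Col1a1 0.64 ± 0.12. The fibroblast median was 0.34, with adjusted p = 4.7e-08, and adjusted p = 0.121 with an estimated correlation. Of the intestinal stem cell list, 3 of 11 measured members fell over all genes and 3 adjusted over the list alone, with Lgr5 -0.77 ± 0.13, Lrig1 -0.36 ± 0.084 and Cdca7 -0.27 ± 0.085. The intestinal stem cell median was -0.23, with adjusted p = 0.0186, and adjusted p = 0.204 with an estimated correlation. For oxidative phosphorylation, 5 of 17 measured members fell over all genes and 7 adjusted over the list alone. The oxidative phosphorylation median was -0.12, with adjusted p = 0.00233, and adjusted p = 0.362 with an estimated correlation. Of the cholesterol synthesis list, 10 of 16 measured members rose over all genes and 12 adjusted over the list alone, with Sc5d 0.32 ± 0.046, Cyp51 0.70 ± 0.12 and Hmgcs1 0.39 ± 0.078. The cholesterol synthesis median was 0.28, with adjusted p = 1.64e-06, and adjusted p = 0.173 with an estimated correlation. The squamous epithelium list, whose keratins mark stratified tissue such as the anal canal, had 7 of 14 members higher and 8 adjusted over the list alone. The squamous epithelium median was 1.34, with adjusted p = 1.24e-05, and adjusted p = 0.295 with an estimated correlation. Its mean per sample was 7.61 ± 1.30 after AOM+DSS and 6.055 ± 1.22 in untreated fl/fl colon (log2, SD, n = 10 each), so samples of a group differed widely in these genes, which include Krt6a and Krt14.

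In knockout mice the same comparison gave 6692 genes, 3538 higher and 3154 lower, of which 344 rose and 34 fell at least 2-fold. Ppbp rose 28.2-fold, Clca4b 16.6-fold, Saa3 15.9-fold and the neutrophil chemokine Cxcl5 12-fold. Within untreated and AOM+DSS knockout colon, Ppbp had log2 SD of 1.86 and 2.28, as wide as the squamous gene Krt6a (1.80 and 2.11). Those of Cxcl5 were 0.32 and 1.11. The 12 largest rises were Ppbp 4.82 ± 0.90, Clca4b 4.06 ± 0.41, Saa3 3.99 ± 0.39, Tmprss11g 3.97 ± 0.70, Krt6a 3.68 ± 0.86, Cxcl5 3.59 ± 0.36, Mcpt1 3.35 ± 0.38, Ltf 3.33 ± 0.71, Tmprss11d 3.32 ± 0.72, Il1b 3.29 ± 0.33, Cxcl3 3.19 ± 0.43 and Khdc1a 3.18 ± 0.33. The 12 largest falls were Mptx1 -2.65 ± 0.33, Ang4 -2.62 ± 0.60, Vsig2 -2.04 ± 0.19, Slc37a2 -1.62 ± 0.26, Fxyd4 -1.58 ± 0.31, Naaladl1 -1.57 ± 0.20, Hao2 -1.48 ± 0.33, Bex4 -1.46 ± 0.14, Mettl7b -1.41 ± 0.19, Otc -1.39 ± 0.26, Cpm -1.36 ± 0.18 and Ces1f -1.27 ± 0.18. Ang4 encodes an antimicrobial ribonuclease and Otc a urea cycle enzyme. Insr fell by 0.30 ± 0.10 (adjusted p = 0.0148) and Irs1 fell by 0.28 ± 0.087 (adjusted p = 0.00925), while Igf1r 0.029 ± 0.092 and Irs2 -0.26 ± 0.14 did not pass.

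Lists of immune cells rose in knockout colon as well. Of the macrophage list, 12 of 12 measured members rose over all genes and 12 adjusted over the list alone. The macrophage median was 0.86, with adjusted p = 7.09e-16, and adjusted p = 0.0446 with an estimated correlation. Of the B cell list, 10 of 10 measured members rose over all genes and 10 adjusted over the list alone, led by Cd22 1.81 ± 0.20, Pax5 1.05 ± 0.12, Fcmr 1.91 ± 0.23 and Cr2 2.58 ± 0.32. The B cell median was 1.73, with adjusted p = 6.37e-13, and adjusted p = 0.0719 with an estimated correlation. Of the T cell list, 11 of 11 measured members rose over all genes and 11 adjusted over the list alone, led by Cd3e 1.60 ± 0.16, Icos 1.04 ± 0.11, Cd3g 1.75 ± 0.20 and Cd4 1.34 ± 0.16. The T cell median was 0.71, with adjusted p = 6.71e-12, and adjusted p = 0.0557 with an estimated correlation. Neutrophil genes included Il1r2 1.91 ± 0.24 and Cxcr2 2.36 ± 0.30, and 9 of 12 measured members rose over all genes and 9 adjusted over the list alone. The neutrophil median was 1.48, with adjusted p = 2.62e-07, and adjusted p = 0.0782 with an estimated correlation. Of the cytokine and chemokine list, 13 of 20 measured members rose over all genes and 13 adjusted over the list alone, with Ccl3 2.06 ± 0.19 and Il1a 1.86 ± 0.23. The inflammatory cytokines and chemokines median was 0.64, with adjusted p = 4.84e-08, and adjusted p = 0.0719 with an estimated correlation. Of the oxidative phosphorylation list, 16 of 17 measured members fell over all genes and 16 adjusted over the list alone, with Ndufv1 -0.37 ± 0.063, Cox4i1 -0.44 ± 0.077, Cox5b -0.36 ± 0.065 and Ndufa9 -0.27 ± 0.056. The oxidative phosphorylation median was -0.23, with adjusted p = 7.21e-07, and adjusted p = 0.138 with an estimated correlation. Of the tuft cell list, 6 of 10 measured members fell over all genes and 7 adjusted over the list alone, with Gnat3 -0.75 ± 0.14, Rgs13 -0.78 ± 0.18, Pou2f3 -0.48 ± 0.12 and Trpm5 -0.41 ± 0.10. The tuft cell median was -0.32, with adjusted p = 0.0123, and adjusted p = 0.295 with an estimated correlation. Part of this fall can rest on untreated replicate 2, whose tuft cell mean was 7.097 where the others lay between 5.875 and 6.284. The list was not tested without it. Squamous genes had a mean of 7.525 ± 1.25 after AOM+DSS and 6.04 ± 0.95 in untreated knockout colon (log2, SD, n = 10 each).

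The AOM+DSS responses of the genotypes share no arrays. Across 22180 genes, which are not independent replicates, their log2 changes had a Pearson r of 0.869 and a Spearman rho of 0.739. Of the passing genes, 2335 were higher and 1349 lower in both genotypes, against 433.1 and 331.2 for independent lists, and 2 passed in opposite directions. Both responses used the same estimate of each gene's spread, so some overlap above that of independent lists can come from it.

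**Figure D2:**
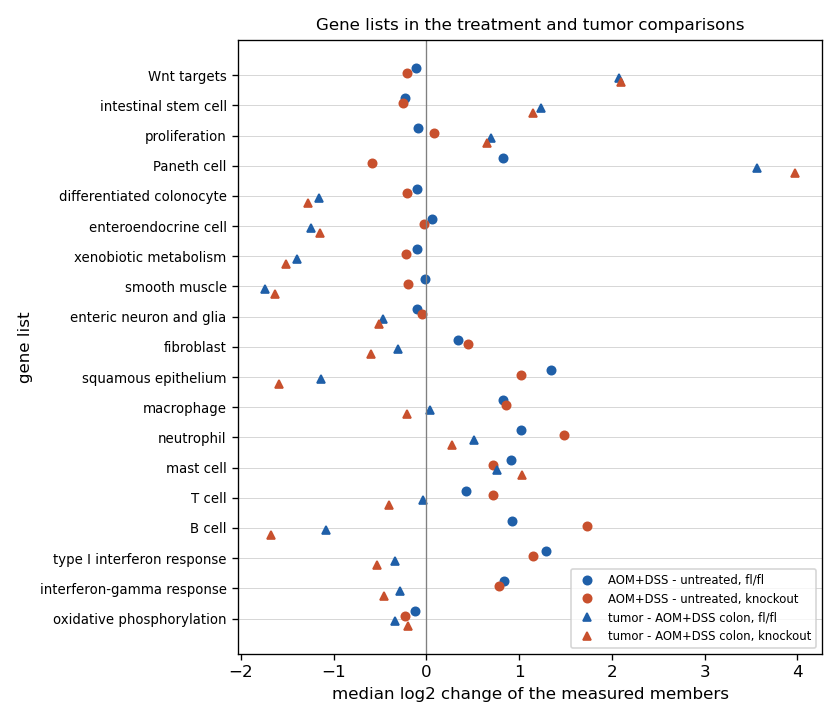
Median log2 change of the measured members (horizontal axis) of 19 gene lists (vertical axis) in the AOM+DSS comparison (circles) and the tumor comparison (triangles), in fl/fl (blue) and knockout mice (red). The Wnt target list had medians of 2.08 and 2.10 in the tumor comparisons, and the smooth muscle list -1.74 and -1.63.

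The second question was how tumors differed from AOM+DSS colon of the same genotype. In fl/fl mice, Notum, a secreted Wnt inhibitor, rose 34.4-fold, the Wnt inhibitor Wif1 35.5-fold, the protease gene Mmp7 43.6-fold and the lipase-related gene Pnliprp1 46.1-fold. The 12 largest rises were Pnliprp1 5.53 ± 0.15, Mmp7 5.45 ± 0.26, Wif1 5.15 ± 0.14, Notum 5.10 ± 0.11, Spock2 4.97 ± 0.12, Prox1 4.82 ± 0.14, Mt4 4.74 ± 0.30, Ang4 4.32 ± 0.64, Pnliprp2 4.31 ± 0.32, Erich3 4.27 ± 0.15, Cfi 4.17 ± 0.15 and Prkg2 4.09 ± 0.25. The 12 largest falls were Cyp2c55 -4.28 ± 0.39, Aqp8 -3.89 ± 0.22, Slc26a3 -3.88 ± 0.30, Car4 -3.56 ± 0.26, Cyp2d13 -3.29 ± 0.21, Car3 -3.27 ± 0.64, Tgm3 -3.27 ± 0.26, Mptx1 -3.26 ± 0.35, Cyp2d12 -3.23 ± 0.27, Insl5 -3.18 ± 0.26, Cyp2c68 -3.13 ± 0.25 and Ces2a -3.11 ± 0.19. Among these, Slc26a3 encodes the chloride-bicarbonate exchanger of the colon surface, Aqp8 a water channel and Car4 a carbonic anhydrase. Insr fell by 0.40 ± 0.10 (adjusted p = 0.00129) and Irs2 fell by 0.46 ± 0.14 (adjusted p = 0.00684), while Igf1r rose by 0.37 ± 0.10 (adjusted p = 0.00124) and Irs1 by 0.32 ± 0.092 (adjusted p = 0.00303).

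In total, 9143 genes passed in fl/fl mice, 4661 higher and 4482 lower, of which 436 rose and 685 fell at least 2-fold. With the smooth muscle list's mean as a covariate, chosen after seeing the data, the count was 1979, and Car3 and Irs2, which fell without it, were 0.34 ± 1.18 and 0.056 ± 0.286. Squamous epithelium genes had a mean of 6.32 ± 0.99 in tumors (n = 8) and 7.61 ± 1.30 in colon (n = 10), as log2 with SD, and 6 of 14 measured members fell over all genes and 6 adjusted over the list alone. The squamous epithelium median was -1.14, with adjusted p = 0.0528, and adjusted p = 0.804 with an estimated correlation.

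Of the Wnt targets, 20 of 20 measured members rose over all genes and 20 adjusted over the list alone, led by Notum 5.10 ± 0.11, Wif1 5.15 ± 0.14, Prox1 4.82 ± 0.14 and Nkd1 3.36 ± 0.12. The Wnt targets median was 2.08, with adjusted p = 1.24e-31, and adjusted p = 8.98e-05 with an estimated correlation. Of the intestinal stem cell list, which shares several members with it, 8 of 11 measured members rose and 2 fell over all genes, or 8 and 2 adjusted over the list alone, with Lgr5 3.37 ± 0.14, Axin2 2.45 ± 0.10, Tnfrsf19 2.16 ± 0.10 and Smoc2 1.77 ± 0.10. The intestinal stem cell median was 1.24, with adjusted p = 7.19e-07, and adjusted p = 0.0113 with an estimated correlation. Of the proliferation list, 17 of 17 measured members rose over all genes and 17 adjusted over the list alone, with Mcm2 0.80 ± 0.10, Top2a 0.95 ± 0.14, Pcna 0.54 ± 0.083 and Aurka 0.74 ± 0.12. The proliferation median was 0.70, with adjusted p = 1.41e-06, and adjusted p = 0.282 with an estimated correlation. Of the Paneth cell list, 5 of 7 measured members rose over all genes and 5 adjusted over the list alone, with Mmp7 5.45 ± 0.26, Pla2g2a 3.39 ± 0.26, Lyz1 3.57 ± 0.35 and Itln1 4.02 ± 0.47. The Paneth cell median was 3.56, with adjusted p = 1.54e-04, and adjusted p = 0.108 with an estimated correlation. Matrix proteases included Mmp12 3.26 ± 0.18, Mmp10 3.22 ± 0.23 and Mmp13 2.71 ± 0.28, and 10 of 12 measured members rose over all genes and 10 adjusted over the list alone. The matrix remodelling proteases median was 1.0, with adjusted p = 3.19e-07, and adjusted p = 0.0899 with an estimated correlation. Of the cytokines and chemokines, 13 of 20 measured members rose over all genes and 13 adjusted over the list alone, with Il23a 3.21 ± 0.11, Tnf 1.5 ± 0.15 and Cxcl1 1.45 ± 0.16. The inflammatory cytokines and chemokines median was 0.92, with adjusted p = 1.85e-05, and adjusted p = 0.109 with an estimated correlation.

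In fl/fl tumors, of the differentiated colonocyte list, 16 of 19 measured members fell and 1 rose over all genes, or 16 and 1 adjusted over the list alone, with Aqp8 -3.89 ± 0.22, Car4 -3.56 ± 0.26, Slc26a3 -3.88 ± 0.30 and Scnn1a -1.29 ± 0.11. The differentiated colonocyte median was -1.16, with adjusted p = 9.09e-10, and adjusted p = 0.0532 with an estimated correlation. Of the enteroendocrine list, 11 of 16 measured members fell and 2 rose over all genes, or 13 and 2 adjusted over the list alone, with the peptide hormone genes Pyy -2.19 ± 0.15 and Gcg -2.28 ± 0.17 and the granule genes Scg3 -1.59 ± 0.12 and Chgb -2.14 ± 0.17. The enteroendocrine cell median was -1.24, with adjusted p = 7.76e-08, and adjusted p = 0.0319 with an estimated correlation. Of the xenobiotic metabolism list, 13 of 16 measured members fell and 1 rose over all genes, or 13 and 1 adjusted over the list alone, with Abcb1a -2.48 ± 0.16, Sult1a1 -2.95 ± 0.21, Cyp3a13 -2.77 ± 0.21 and Cyp2s1 -2.17 ± 0.17. The xenobiotic metabolism median was -1.39, with adjusted p = 7.05e-09, and adjusted p = 0.0532 with an estimated correlation. Of the smooth muscle list, 13 of 13 measured members fell over all genes and 13 adjusted over the list alone, with Lmod1 -1.85 ± 0.13, Pgm5 -2.38 ± 0.17, Tagln -1.66 ± 0.13 and Synm -2.22 ± 0.17. The smooth muscle median was -1.74, with adjusted p = 3.69e-16, and adjusted p = 0.0532 with an estimated correlation. The list's mean was 9.565 ± 0.38 in tumors (n = 8) and 11.25 ± 0.25 in colon (n = 10), as log2 with SD. Of the enteric neuron and glia list, 11 of 14 measured members fell and 1 rose over all genes, or 11 and 1 adjusted over the list alone, with Snap25 -2.08 ± 0.16, Stmn2 -1.86 ± 0.14, Vip -1.64 ± 0.16 and Prph -0.95 ± 0.094. The enteric neuron and glia median was -0.47, with adjusted p = 1.3e-05, and adjusted p = 0.0438 with an estimated correlation. Of the B cell list, 10 of 10 measured members fell over all genes and 10 adjusted over the list alone, with Fcmr -1.53 ± 0.24 and Cr2 -1.91 ± 0.33. The B cell median was -1.08, with adjusted p = 1.74e-04, and adjusted p = 0.385 with an estimated correlation.

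In knockout mice, 9511 genes passed between tumor and AOM+DSS colon, 4761 higher and 4750 lower, of which 382 rose and 723 fell at least 2-fold. With the smooth muscle covariate the count was 2053, and Krt6a, Ppbp and Tmprss11a, which fell without it, were 0.36 ± 1.75, 0.28 ± 1.85 and 0.13 ± 1.38. The 12 largest rises were Pnliprp1 5.45 ± 0.15, Notum 5.07 ± 0.11, Wif1 5.05 ± 0.14, Mmp7 5.04 ± 0.25, Spock2 5.04 ± 0.12, Ang4 4.71 ± 0.62, Prox1 4.71 ± 0.14, Mt4 4.64 ± 0.29, Pnliprp2 4.49 ± 0.31, Erich3 4.46 ± 0.15, Itln1 4.41 ± 0.45 and Defa35 4.36 ± 0.41, of which Itln1 encodes a lectin and Defa35 a defensin. The 12 largest falls were Slc26a3 -4.21 ± 0.29, Cyp2c55 -4.11 ± 0.38, Aqp8 -3.64 ± 0.22, Tmprss11a -3.20 ± 0.71, Tmprss11d -3.14 ± 0.74, Tmprss11g -3.12 ± 0.72, Ppbp -3.04 ± 0.92, Cyp2d13 -3.02 ± 0.21, Car4 -2.99 ± 0.25, Krt6a -2.95 ± 0.88, Cyp2c68 -2.87 ± 0.24 and Fmo2 -2.84 ± 0.19. Squamous epithelium genes, which include Krt6a, had a mean of 6.09 ± 0.90 in tumors (n = 9) and 7.525 ± 1.25 in colon (n = 10), as log2 with SD, and 8 of 14 measured members fell over all genes and 11 adjusted over the list alone. The squamous epithelium median was -1.59, with adjusted p = 0.0360, and adjusted p = 0.750 with an estimated correlation. With that list's mean, to which Krt6a itself contributes, as a covariate, Krt6a was -0.64 ± 0.41 (adjusted p = 0.236) and Ppbp -0.67 ± 0.48 (adjusted p = 0.293), and neither passed. Insr was -0.21 ± 0.10 (adjusted p = 0.0903) and Irs2 fell by 0.74 ± 0.14 (adjusted p = 1.11e-05). Irs1 rose by 0.25 ± 0.090 (adjusted p = 0.0201) and Igf1r, at 0.092 ± 0.095, did not pass.

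In knockout tumors, for Wnt targets, 20 of 20 measured members rose over all genes and 20 adjusted over the list alone, and for intestinal stem cell genes 8 of 11 measured members rose and 1 fell over all genes, or 8 and 2 adjusted over the list alone, with Nkd1 3.59 ± 0.12, Axin2 2.58 ± 0.10 and Lgr5 3.15 ± 0.13. The Wnt targets median was 2.10, with adjusted p = 1.57e-31, and adjusted p = 9.26e-05 with an estimated correlation. The intestinal stem cell median was 1.15, with adjusted p = 1.6e-07, and adjusted p = 0.00590 with an estimated correlation. For Paneth cell genes, 7 of 7 measured members rose over all genes and 7 adjusted over the list alone, with Pla2g2a 3.28 ± 0.25 and Lyz1 3.98 ± 0.34. The Paneth cell median was 3.98, with adjusted p = 3.44e-06, and adjusted p = 0.0533 with an estimated correlation. For differentiated colonocyte genes, 17 of 19 measured members fell and 1 rose over all genes, or 17 and 1 adjusted over the list alone. The differentiated colonocyte median was -1.27, with adjusted p = 2.79e-10, and adjusted p = 0.0533 with an estimated correlation. For enteroendocrine genes, 14 of 16 measured members fell and 1 rose over all genes, or 14 and 1 adjusted over the list alone, with Scg3 -1.56 ± 0.12, Chgb -2.09 ± 0.16, Pyy -1.90 ± 0.15 and Gcg -2.13 ± 0.17. The enteroendocrine cell median was -1.15, with adjusted p = 8.75e-08, and adjusted p = 0.0248 with an estimated correlation. For smooth muscle genes, 13 of 13 measured members fell over all genes and 13 adjusted over the list alone, with a mean of 9.43 ± 0.48 in tumors (n = 9) and 11.08 ± 0.21 in colon (n = 10), as log2 with SD. The smooth muscle median was -1.63, with adjusted p = 6.58e-15, and adjusted p = 0.0621 with an estimated correlation. For enteric neuron and glia genes, 12 of 14 measured members fell and 1 rose over all genes, or 12 and 1 adjusted over the list alone. The enteric neuron and glia median was -0.51, with adjusted p = 2.44e-06, and adjusted p = 0.0248 with an estimated correlation. For B cell genes, 10 of 10 measured members fell over all genes and 10 adjusted over the list alone. The B cell median was -1.67, with adjusted p = 3.1e-07, and adjusted p = 0.192 with an estimated correlation.

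Tumor responses of the genotypes had a Pearson r of 0.947 and a Spearman rho of 0.859 across genes. Of the passing genes, 3806 were higher and 3772 lower in both, against 1000 and 959.9 for independent lists, and 3 passed in opposite directions. The shared estimate of spread limits this comparison too.

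The third question was what the loss of Insr changed within each condition. In untreated colon, Insr was the 1 gene that passed, with 1114 genes at an unadjusted p under 0.05 where 1109 were expected by chance. Camera called 13 lists, and neither the estimated correlation nor fry called any. The macrophage list was among the 13, with 0 of its 12 measured members past the threshold over all genes and 5 adjusted over the list alone. The macrophage median was 0.24, with adjusted p = 5.98e-10, and adjusted p = 0.282 with an estimated correlation. The count of genes was 5 when the untreated groups alone were fitted, 10 with array weights and 4 without the knockout array that stood apart.

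After AOM+DSS, 120 genes differed between the genotypes, 93 higher and 27 lower in knockout colon. The 12 largest rises were led by Chrdl2, a BMP inhibitor gene, and held the leukocyte genes Ptprc, Stat4 and Gpr171, with changes of Chrdl2 0.87 ± 0.21, Nlrp1c-ps 0.74 ± 0.17, Stat4 0.72 ± 0.16, Gpr171 0.71 ± 0.16, Arhgap15 0.68 ± 0.15, Ptprc 0.68 ± 0.17, Ly6i 0.66 ± 0.16, Igfbp5 0.65 ± 0.15, Il5ra 0.62 ± 0.14, Gpr65 0.61 ± 0.14, Fcrl1 0.61 ± 0.15 and Spon1 0.60 ± 0.14. The 12 largest falls were Mptx1 -1.33 ± 0.33, Naaladl1 -0.88 ± 0.20, Insr -0.84 ± 0.10, Clps -0.79 ± 0.19, Klb -0.78 ± 0.15, Pm20d1 -0.68 ± 0.12, Rims4 -0.63 ± 0.11, Cyp2c40 -0.60 ± 0.14, Igsf23 -0.54 ± 0.14, Upk1a -0.52 ± 0.13, Slc4a4 -0.51 ± 0.12 and Slc25a34 -0.50 ± 0.11. Klb encodes the coreceptor of endocrine fibroblast growth factors, Clps the lipase cofactor colipase and Slc4a4 a bicarbonate cotransporter. At least 2-fold changes were found for 3 genes, all lower. The number depended strongly on the model, with 2 genes, both lower, when the AOM+DSS groups alone were fitted, 485 with array weights, and 24 higher and 21 lower after a shift to 1 median. The SE above pool the spread of all 6 groups, which was not equal. Il5ra had SD of 0.48 and 0.46 in fl/fl and knockout AOM+DSS colon and at most 0.26 elsewhere, so its SE understates the spread after AOM+DSS. Insr went the other way, with its largest SD in knockout tumors (0.36). With the B and T cell list means as covariates, chosen after seeing the data, 2 genes passed.

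Between the genotypes after AOM+DSS, camera called 15 lists higher and 10 lower in the knockout at the preset correlation, and none with an estimated correlation. The T cell list had Icos (0.49 ± 0.11) as its 1 member past the threshold over all genes and 9 of 11 adjusted over the list alone. The T cell median was 0.35, with adjusted p = 3.67e-09, and adjusted p = 0.107 with an estimated correlation. The B cell list had 0 of 10 over all genes and 10 adjusted over the list alone, with Cd22 0.71 ± 0.20, Blk 0.49 ± 0.16, Cr2 0.89 ± 0.32 and Pax5 0.33 ± 0.12. The B cell median was 0.60, with adjusted p = 1.59e-08, and adjusted p = 0.185 with an estimated correlation. Its mean was 7.90 ± 0.22 in knockout and 7.29 ± 0.64 in fl/fl samples (log2, SD, n = 10 each). Matrix proteases had Mmp2 (0.44 ± 0.10) past the threshold and 8 of 12 adjusted over the list alone. The matrix remodelling proteases median was 0.40, with adjusted p = 1.72e-08, and adjusted p = 0.107 with an estimated correlation. The IGF axis had Igfbp4 0.53 ± 0.11 and Igfbp5 0.65 ± 0.15 past the threshold, with 5 of 11 higher and 2 lower adjusted over the list alone. The IGF axis median was 0.20, with adjusted p = 0.0104, and adjusted p = 0.196 with an estimated correlation. Oxidative phosphorylation had 0 of 17 over all genes and 13 lower adjusted over the list alone, with Cox5b -0.22 ± 0.065 and Ndufs3 -0.17 ± 0.051. The oxidative phosphorylation median was -0.14, with adjusted p = 5.3e-10, and adjusted p = 0.107 with an estimated correlation. Fry called 10 of the 46 lists, the T cell (adjusted p = 0.0106) and B cell lists (adjusted p = 0.0324) among them.

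**Figure D3:**
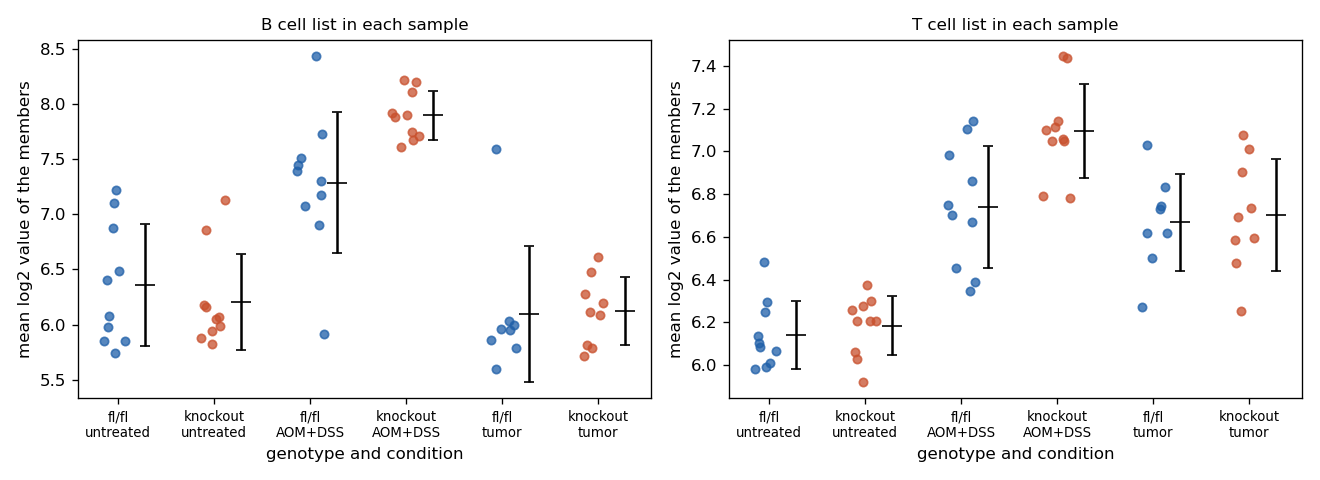
Mean log2 value of the measured members of the B cell (left) and T cell list (right) on the vertical axis in each sample by genotype and condition, with points for samples and bars for the mean ± SD. After AOM+DSS the B cell mean was 7.29 in fl/fl and 7.90 in knockout colon, and the T cell mean 6.74 and 7.10.

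In tumors, Insr and the predicted gene Gm17250, named after its values were seen, were the 2 genes that passed, both lower in the knockout. The Gm17250 call was lost without dim genes, with the replicate block and without knockout untreated replicate 2, where Insr alone passed. At an unadjusted p under 0.05 there were 990 genes where 1109 were expected, and with the tumors alone limma called 0, with 832 at an unadjusted p under 0.05. Camera called 13 lists and neither the estimated correlation nor fry called any. Of the proliferation list, 0 of 17 members passed over all genes or adjusted over the list alone. The proliferation median was 0.20, with adjusted p = 3.23e-09, and adjusted p = 0.489 with an estimated correlation. Of the differentiated colonocyte list, 0 of 19 passed over all genes and 3 were lower adjusted over the list alone. The differentiated colonocyte median was -0.19, with adjusted p = 5.24e-05, and adjusted p = 0.489 with an estimated correlation.

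The difference between the genotypes in their responses was tested as an interaction. For the AOM+DSS response, limma called 0 genes, with 1351 at an unadjusted p under 0.05 where 1109 were expected. The 5 genes with the smallest p did not pass, at Tiam2 -0.46 ± 0.11, Treml2 0.84 ± 0.21, Pm20d1 -0.70 ± 0.18, Klhl23 -0.45 ± 0.11 and Ikzf4 0.46 ± 0.12 (smallest adjusted p = 0.576). Insr had 0.094 ± 0.14, Igf1r -0.040 ± 0.13, Irs1 -0.16 ± 0.12 and Irs2 -0.30 ± 0.19. For the tumor response limma called 0 genes, with 1470 at an unadjusted p under 0.05. A fit on the compared groups alone called 1 gene, and the replicate block 1, both with a negative difference. In the main fit the 5 with the smallest p did not pass, at Ica1l -0.56 ± 0.12, Il5ra -0.98 ± 0.21, Prrg1 -0.66 ± 0.14, Apoe -0.45 ± 0.10 and Dusp22 -0.65 ± 0.15 (smallest adjusted p = 0.186). Values for the 4 receptor and adaptor genes were Insr 0.19 ± 0.15, Igf1r -0.28 ± 0.14, Irs1 -0.077 ± 0.13 and Irs2 -0.28 ± 0.20. Of the lists, camera called 19 for the AOM+DSS response and 11 for the tumor response, and neither the estimated correlation nor fry called any. The B cell list, with 0 of 10 members past the threshold over all genes and 7 higher adjusted over the list alone, was higher in the knockout response to AOM+DSS. The B cell median was 0.79, with adjusted p = 2.05e-09, and adjusted p = 0.333 with an estimated correlation. The larger count of genes in knockout colon after AOM+DSS is therefore not shown to be a difference between genotypes.

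Over the mean of the 3 conditions, 24 genes differed, 7 higher and 17 lower in knockout samples. Those higher were Socs3, an inhibitor of cytokine signalling, the metallothionein gene Mt1 and 5 others, at Socs3 0.42 ± 0.092, Mt1 0.29 ± 0.046, Cdk14 0.25 ± 0.053, Tmem176a 0.19 ± 0.041, Hdac9 0.19 ± 0.041, Tln2 0.19 ± 0.042 and Tec 0.16 ± 0.038. The 12 largest falls were Insr -0.81 ± 0.059, Cyp2c68 -0.62 ± 0.14, Clps -0.53 ± 0.11, Klb -0.46 ± 0.090, Eno3 -0.38 ± 0.085, Upb1 -0.34 ± 0.077, Slc25a34 -0.32 ± 0.067, Rims4 -0.32 ± 0.068, Cdkn2b -0.28 ± 0.054, Ugdh -0.26 ± 0.052, Pik3r3 -0.26 ± 0.046 and Coq10a -0.20 ± 0.045, of which Pik3r3 encodes a regulatory subunit of PI3 kinase and Cdkn2b a cell cycle inhibitor. No gene changed 2-fold, and Igf1r 0.14 ± 0.055, Irs1 0.057 ± 0.052 and Irs2 0.24 ± 0.081 did not pass. A change of this mean need not be present in each condition. Tumor means, fl/fl then knockout, were nearly equal for Klb (5.616 and 5.609), Cdk14 (6.825 and 6.836), Tln2 (7.555 and 7.571) and Tec (8.385 and 8.405). They lay further apart for Pik3r3 (9.524 and 9.324), Socs3 (8.598 and 8.921) and Insr (8.183 and 7.53). The count was 14 after a shift to 1 median. With array weights it was 84, and the balance turned to 54 higher and 30 lower. Camera called 24 lists, the estimated correlation none (smallest adjusted p = 0.0828) and fry 3.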

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

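The tests with the squamous, distal position, lymphoid, smooth muscle and colonocyte lists and the tests on small-intestinal transcripts were chosen only after the result was seen, whereas the splits of the samples and the test on the neighbours of Insr were set before. Of 312 searches for a sample far from the rest of its group, 34 found one, where chance gives about 1 in 20, or 15.6.

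The first pattern weighed was the 120 genes that differed between the genotypes after AOM+DSS. The squamous epithelium mean differed by -0.0849 ± 0.569 (SE), knockout minus fl/fl, where the slopes of these genes on it within groups would need a median difference of 14.8 (quartiles 8.49 and 41.3) to give their changes. The distal colon position mean differed by -0.0729 ± 0.105, where 9.17 (5.1 and 17.2) would be needed, which argues against squamous tissue or position along the colon as the whole cause. With the B cell and T cell covariates, the 119 genes outside those lists kept 62.7% (39.5 and 78.3%), and 2 genes passed in place of 120, so a larger share of lymphoid cells in the knockout samples may account for part of the difference and cannot be told apart from a change within cells. The lymphoid covariates differ with genotype (B cell mean 7.90 in knockout and 7.29 in fl/fl samples), which keeps this open. The shift was not particular to them, since in the same order the means of macrophage (9.541 and 9.276), neutrophil (6.951 and 6.606), eosinophil (5.973 and 5.762), fibroblast (10.38 and 10.18) and endothelial genes (8.086 and 7.908) were larger too and that of smooth muscle smaller (11.08 and 11.25), and genotype, the biological difference in the design, stays open too.

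The second pattern was the fall of smooth muscle and enteric neuron genes in tumors, which could come from tumors sampled with less muscle and may extend to other genes. With the smooth muscle covariate, the 7565 genes called in both genotypes, outside the list itself, kept a median of 65.6% of their change (quartiles 35.8 and 93.1%), so less muscle and a change within cells cannot be told apart over all of them, since the covariate is confounded with the tumor groups. The 20 Wnt targets kept 97.9% (93.4 and 102%), which argues against less muscle as the source of their rise. Less muscle alone would raise the share of epithelium. That rise was not seen, since the pan-epithelial mean was 10.92 in tumors and 11.12 in AOM+DSS colon of fl/fl mice, and 10.84 and 11.05 in knockout mice. The 19 differentiated colonocyte genes had a median change of -1.2 over both genotypes (quartiles -1.74 and -0.72). This argues against less muscle alone as the source of their fall, although the 17 of them called in both kept 71.3% with the covariate. Tumor growth itself stays an open biological explanation.

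The third pattern was a group of small-intestinal transcripts that were high in single colon samples. A list of 20 transcripts, of which 14 lay above the median gene in untreated fl/fl colon and 0 belonged to a list fixed earlier, reached 11.14 in fl/fl AOM+DSS replicate 7, where the others lay between 7.44 and 8.302, with Sis at 12.02, Fabp1 at 11.11 and Alpi at 12.1. Knockout samples were high too, with AOM+DSS replicate 10 at 10.13 (Sis 11.33, Fabp1 9.247, Alpi 10.87) and untreated replicates 4 and 7 at 9.205 and 9.154. If such samples had been taken further from the anus, the list should fall as the distal position list rises. Across the 40 colon samples the relation had a Pearson r of -0.143 (permutation p = 0.401, adjusted p = 0.401) and a Spearman rho of -0.237 (permutation p = 0.116, adjusted p = 0.156), so position may or may not contribute. In the order named, the distal position means of the high samples differed from their groups by -0.198, -0.0972, 0.265 and 0.0362. Low distal position genes were thus not common to these samples. Knockout untreated replicate 2, at -1.41 for distal position, had a small-intestinal difference of -0.103. In tumors, fl/fl replicate 6, with a small-intestinal mean of 9.199, was at -0.656 for distal position. Without the 2 samples farthest from the median of the group-centred distal position list, r was -0.342. The samples with the highest small-intestinal values stayed in. With the Paneth cell list r was 0.664 (permutation p = 2e-05, adjusted p = 8e-05) and rho 0.593 (permutation p = 0.00031, adjusted p = 0.00124), over 4 relations computed. Without the 2 samples farthest on the Paneth cell list, r was 0.504. No biological explanation was tested.

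Other splits of the samples were drawn, 100 per comparison with the real one. For AOM+DSS against untreated colon, 1 split, the real one, gave as many genes as the real 5044 in fl/fl mice (highest other 1795) and 1 gave as many as 6692 in knockout mice (1130). For tumors against colon, 1 split gave as many as 9143 in fl/fl (5105) and 1 as many as 9511 in knockout mice (7704). Splits that leave most samples in their real group keep part of the difference. For genotype, 2 splits gave as many as 120 genes after AOM+DSS (highest other 821), and 1 as many as 24 over the 3 conditions (2). These shares lie under 0.05, not adjusted over the comparisons, and make a chance split of the mice less likely without excluding it. The splits left chance open for the size of the other counts, 1 gene in untreated colon (7 splits, highest other 72) and 2 genes in tumors (32 splits, 903). For Insr itself, called in both, the permutation test gave p = 2e-05 in untreated colon and exact p = 0.00169 in tumors. For the interactions the real count was 0, which all 100 splits reach by necessity (highest other 17 and 2), so the splits decided nothing. The splits that called 821 and 903 genes lie far above the real counts of 120 and 2, which points to a structure of those samples that was not traced.

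Samples far from their groups were found for the following list means, given with the range of the others. Knockout untreated replicate 2 had goblet cell 11.91 (10.38 to 11.16), enteroendocrine 8.083 (7.463 to 7.726), tuft cell 7.097 (5.875 to 6.284) and distal colon position 6.689 (8.138 to 8.366), and a mean correlation of 0.9815 with its group (0.9866 to 0.9907). Knockout tumor replicate 6 had goblet cell 9.712 (10.27 to 10.7), endothelial 8.189 (7.4 to 7.794), adipocyte 6.936 (5.721 to 6.281) and squamous epithelium 8.351 (5.505 to 6.547). The fl/fl tumor replicate 6 had tuft cell 6.325 (6.089 to 6.194), Paneth cell 11.73 (9.79 to 10.26) and small intestine 9.199 (6.756 to 7.49). In the other fl/fl tumors, replicate 3 had B cell 7.589 (5.598 to 6.031), replicate 4 eosinophil 6.103 (5.749 to 5.91) and squamous epithelium 8.571 (5.566 to 6.76), and replicate 2 adipocyte 7.287 (5.836 to 6.409). The fl/fl AOM+DSS replicate 4 had macrophage 9.737 (8.957 to 9.363), endothelial 8.45 (7.653 to 8.012) and matrix proteases 8.471 (6.853 to 7.715), and replicate 7 FoxO targets 9.107 (8.693 to 8.865). Knockout AOM+DSS replicate 2 had fetal and regenerative epithelium 8.737 (9.013 to 9.314) and cytokines and chemokines 5.54 (6.185 to 6.852). Knockout untreated replicate 5 had glycolysis 10.1 (9.843 to 9.941), interferon-gamma response 9.831 (7.761 to 8.862) and type I interferon response 7.963 (6.766 to 7.207). The fl/fl untreated replicate 4 had interferon-gamma response 8.841 (7.614 to 8.026), type I interferon response 7.619 (6.493 to 7.008) and xenobiotic metabolism 9.499 (9.643 to 9.734). Other fl/fl untreated samples were replicate 1 with skeletal muscle 6.199 (5.576 to 5.788), replicate 2 with cholesterol synthesis 10.06 (9.428 to 9.764), replicate 3 with fatty acid oxidation 9.709 (9.388 to 9.558), replicate 5 with Paneth cell 7.751 (6.156 to 6.938) and replicate 10 with small intestine 8.599 (7.314 to 7.691). The small intestine list was added to this search after the first samples far from their groups had been seen.

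The difference between the genotypes in a list's response, knockout minus fl/fl, passed camera's interaction test at the preset correlation for 19 lists after AOM+DSS and 11 in tumors, and for 0 with an estimated correlation (smallest adjusted p = 0.333 and 0.482). Medians of the AOM+DSS difference were positive for neutrophil 0.436, T cell 0.333, B cell 0.786, fibroblast 0.144, endothelial 0.138, proliferation 0.17, cytokines and chemokines 0.307 and matrix proteases 0.292. They were negative for differentiated colonocyte -0.185, goblet cell -0.149, tuft cell -0.173, Paneth cell -1.43, smooth muscle -0.235, adipocyte -0.406, skeletal muscle -0.46, lipogenesis -0.117, cholesterol synthesis -0.0725, oxidative phosphorylation -0.126 and xenobiotic metabolism -0.201. The Paneth cell list varied widely, with 7.557 ± 1.12 (SD, n = 10) and up to 9.769 in fl/fl AOM+DSS colon. It rose with the small-intestinal transcripts across colon samples (Pearson r of 0.664, centred by group). Knockout untreated replicate 2, far above its group for goblet and tuft cell genes, lies in the baseline of those differences. No list test was run without such samples. Medians of the tumor difference were macrophage -0.234, T cell -0.327, B cell -0.594, eosinophil -0.154, fibroblast -0.164, endothelial -0.174, IGF axis -0.186, interferon-gamma response -0.23 and type I interferon response -0.266, and positive for fatty acid oxidation 0.172 and oxidative phosphorylation 0.138. The B cell difference includes fl/fl tumor replicate 3, with a list mean of 7.589 where the others lay between 5.598 and 6.031. It was not tested without that sample.

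Of the 16010 probe sets without a gene name here, limma called 695 for AOM+DSS in fl/fl and 906 in knockout mice, 1636 for tumors in fl/fl and 1489 in knockout mice. Between the genotypes it called 7 in untreated colon, 7 after AOM+DSS and 4 in tumors.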

How the results depend on the processing

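The alternatives that left out an array or added a list as a covariate were tests chosen only after the result was seen. Of 3394 alternative values of the 299 named gene results, 3254 kept their direction and side of the threshold, 125 (of 64 results) lost the call, 5 (of 4) gained it and 10 reversed. The counts for AOM+DSS against untreated colon stayed within 1.5 times under every alternative run, and those for tumors under all but the smooth muscle covariate (1979 in fl/fl and 2053 in knockout mice). The lowest AOM+DSS counts came with the squamous covariate, 3408 in fl/fl mice, of which 3149 were called without it, and 5461 in knockout mice. Further quantile normalization gave 2 genes for genotype in untreated colon. A shift to 1 median gave 45 for genotype after AOM+DSS and 14 over the 3 conditions. Without dim genes (under 5.989, 13131 genes kept) the genotype counts were 2 in untreated colon, 242 after AOM+DSS, 1 in tumors and 41 over the conditions, with fewer genes to adjust for. With the compared groups alone they were 5, 2 and 0 (832 tumor genes at an unadjusted p under 0.05 in limma), and the tumor interaction had 1. These fits take the spread from fewer arrays and from the compared groups only. For Insr the SE was 0.0719 in untreated colon, 0.0839 after AOM+DSS and 0.139 in tumors. With all groups it was 0.0985, 0.0985 and 0.107, so the spread of this gene differed between conditions. Array weights gave 10, 485 and 1, and 84 over the conditions. The replicate block gave 2, 188 and 1, and 1 for the tumor interaction. Without the array that stood apart, knockout untreated replicate 2, there were 4 in untreated colon and 1 in tumors. The squamous covariate gave 216 after AOM+DSS and 40 over the conditions, the B and T cell covariates 2 after AOM+DSS, and the mean of a gene's probe sets 15 over the conditions. Insr in tumors was -0.6529 (adjusted p = 1) with the tumors alone and -0.5889 (adjusted p = 0.087) with array weights, and its adjusted p under the other alternatives lay between 0.000454 and 0.00301. With an estimated correlation 10 of 175 list calls in 9 comparisons held. Reversed values were Igf1r after AOM+DSS -0.048 in fl/fl and -0.083 in knockout mice with the squamous covariate, and Irs2 -0.028 in fl/fl and Igf1r -0.021 in knockout mice after further quantile normalization, none of which had passed. With the smooth muscle covariate in tumors, Car3 was 0.34 and Irs2 0.056 in fl/fl mice, and Insr 0.095, Krt6a 0.36, Ppbp 0.28 and Tmprss11a 0.13 in knockout mice. The cause was not tested where none is given. The scalings moved the median of all genes by at most 0.0411. Replicate numbers were not shown to pair the samples. Centred by group, 5 of 57 arrays correlated best with an array of their own number, sought over all other groups. Pairs of the same number had a mean correlation of 0.0387, with 41 of 136 over 0.1, and other pairs -0.00431. Pairing or a shared batch within some groups is therefore not ruled out. Dim transcripts near the background limit what these arrays can show.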

Other observations

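The relation of Insr with the pan-epithelial list was a test chosen only after the result was seen for Insr, whereas the lists and the test on the neighbours of Insr were set before. After AOM+DSS, of the epithelial antimicrobial defence list in fl/fl colon, 6 of 10 measured members rose over all genes and 6 adjusted over the list alone, with the protease inhibitor gene Slpi 1.49 ± 0.16 and the nitric oxide synthase gene Nos2 1.90 ± 0.32. The epithelial antimicrobial defence median was 0.97, with adjusted p = 5.02e-06, and adjusted p = 0.0819 with an estimated correlation. In knockout colon 6 of 10 measured members rose and 1 fell over all genes, or 6 and 1 adjusted over the list alone, with Slpi 1.85 ± 0.16 and Lcn2 1.71 ± 0.22. The epithelial antimicrobial defence median was 1.20, with adjusted p = 5.83e-05, and adjusted p = 0.0782 with an estimated correlation. Genes of fetal and regenerative epithelium included Anxa1 0.97 ± 0.13, Krt7 0.45 ± 0.073 and Clu 0.46 ± 0.13 in fl/fl colon, where 4 of 10 measured members rose over all genes and 5 adjusted over the list alone. The fetal and regenerative epithelium median was 0.37, with adjusted p = 4.12e-04, and adjusted p = 0.0756 with an estimated correlation.

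Of the goblet cell list in fl/fl tumors, 8 of 16 measured members fell and 2 rose over all genes, or 11 and 2 adjusted over the list alone, with Atoh1 -1.27 ± 0.13, Muc3 -1.23 ± 0.13 and Fcgbp -1.12 ± 0.14. The goblet cell median was -0.46, with adjusted p = 0.00485, and adjusted p = 0.544 with an estimated correlation. In knockout tumors 11 of 16 measured members fell and 2 rose over all genes, or 11 and 2 adjusted over the list alone. The goblet cell median was -0.52, with adjusted p = 0.00926, and adjusted p = 0.632 with an estimated correlation. FoxO targets moved in both directions, and in fl/fl mice 10 of 16 measured members fell and 5 rose over all genes, or 10 and 5 adjusted over the list alone, with Fbxo32 -1.55 ± 0.12 and Ccng2 -0.98 ± 0.082. The FoxO targets median was -0.44, with adjusted p = 0.00815, and adjusted p = 0.0764 with an estimated correlation. Of the distal colon position list, 5 of 7 measured members fell over all genes and 5 adjusted over the list alone in fl/fl tumors, with Hoxb13 -0.79 ± 0.14 and Hoxa13 -0.38 ± 0.10. The distal colon position median was -0.79, with adjusted p = 0.0775, and adjusted p = 0.544 with an estimated correlation. Of the fl/fl tumors, replicates 2, 6 and 7 had list means of 6.382, 6.888 and 6.366, where the other 5 lay between 7.931 and 8.346 and fl/fl AOM+DSS colon averaged 8.259. In knockout tumors 2 of 7 measured members fell over all genes and 2 adjusted over the list alone, with a mean of 7.781 (replicate 1 at 6.326) where knockout AOM+DSS colon averaged 8.186. The distal colon position median was -0.49, with adjusted p = 0.284, and adjusted p = 0.763 with an estimated correlation. After AOM+DSS the list had 0 of 7 members past the threshold in fl/fl colon over all genes and 0 adjusted over the list alone (adjusted p = 1).

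Genes close to Insr could differ between the genotypes if the DNA around the gene differed between them. Of the 20 tested genes nearest to Insr on its chromosome, all on 1 side since no tested gene precedes it, limma called 0 over the 3 conditions. At an unadjusted p under 0.05 there were 3 (smallest adjusted p = 0.207, changes from -0.103 to 0.185). The fl/fl mice carry the floxed locus too, so its neighbours need not differ and the test cannot decide whether the called genes were linked to an altered locus. Across samples, centred by group, Insr and the pan-epithelial list had a Pearson r of 0.295 (permutation p = 0.172, adjusted p = 0.344) and a Spearman rho of 0.321 (permutation p = 0.117, adjusted p = 0.156) in 28 fl/fl samples. In 29 knockout samples r was 0.212 (permutation p = 0.375, adjusted p = 0.401) and rho 0.198 (permutation p = 0.338, adjusted p = 0.338). Without the 2 samples farthest from the median of the pan-epithelial list, r was 0.484 and 0.314.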
